A study of Mus musculus with 6 samples.

How the data were processed

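Liver RNA of male C57BL/6 mice was measured in 6 samples, 3 Sesn3 KO and 3 WT. Per the labels, the mice were 4 months old and ate a diet for 4 weeks that gave 20% of its energy as protein, 40% as fat and 40% as carbohydrate and held cholesterol at 1.25% and the bile salt sodium cholate at 0.5%. Per the labels' protocols, RNA was isolated with Trizol from snap-frozen liver and libraries were made with an Illumina TruSeq kit from 1 µg of RNA. The authors deposited a table of whole-number read counts per gene symbol, with 1 column per library and no normalization, which was tested as given. The submitters' processing notes name STAR 2.5, featureCounts, Subread 1.5.3, edgeR 3.20.8 and the genome build mm10. The role of each tool, the gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Genes of multigene families, and overlapping or antisense genes, are uncertain for that reason.

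Libraries were grouped by the genotype in the labels and numbered in accession order, and those numbers pair no samples. Nothing in the labels says more than that these are separate samples, so p-values measure only the spread between these samples. No pair of libraries agreed within sampling noise: the chi-square of counts over genes, divided by its degrees of freedom, was between 21.5 and 134 within groups. Totals ran from 18882220 to 24098512 counts per library. Intervals of ratios cover counting error only. Gene positions were taken from GENCODE mouse release 21 by symbol, with 23334 of 24421 symbols (95.5%) matched to 1 gene.

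Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM factors, glmQLFit with robust dispersion and the two-sided quasi-likelihood F-test of KO minus WT, with Benjamini-Hochberg adjustment over the 12945 genes kept and a threshold of 0.05. CPM values are scaled by TMM factors. Standard errors are approximate, being the log2 fold change divided by the root of F. The common biological coefficient of variation was 0.232. With 3 libraries against 3 an exact permutation test cannot go below 0.10.

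Lists of pathway genes, cell type markers and quality genes, 48 in all, were fixed before the data were examined. The 44 lists with 5 or more tested genes went through camera (limma 3.58.1) with a preset correlation of 0.01, through camera with an estimated correlation and through fry. Members are counted at an adjusted p over all genes and when adjusted over the list alone. Exocrine pancreas (2 tested genes), adipose and muscle (0), the sestrin family (3) and mitochondria-encoded transcripts (0 in the table) were too small to test.

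The genes named in the text were set by a rule fixed before the data were examined: the 3 sestrins, and, among called genes with a mean CPM of at least 1 and no overlap between groups, the 8 with the largest rise, the 8 with the largest fall and the 5 most abundant, leaving out unnamed gene models and antigen receptor segments. From each list that camera called, or that had 3 or more called members, up to 4 genes with the smallest p were added. Of the genes this rule names, 1 is not reported here. Where few members of a list passed, the rest were named after their values were seen: Cd63, Chac1, Clec4f, Col3a1, Crat, Cyp2b10, Cyp4a10, Fabp1, Fosb, Gdf15, Hsd17b13, Ide, Ifi44, Jund, Ltbp3, Nnt, Pigr, Slc1a4, Slc27a5, Slc51b, Sqstm1, Tff3, Tgfb2 and Vsig4.

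The alternatives were RLE and upper-quartile factors, library size only, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust dispersion, a fold or level minimum, and leaving out each library. The script was tested on simulated data for this comparison: with 50 genes changed at each size among 12945, edgeR recovered 6% at 1.5-fold, 44% at 2-fold, 86% at 4-fold and 94% at 8-fold, and 10.2% of its calls were false. DESeq2 recovered 22%, 72%, 92% and 98%, with 26.4% false. In 10 simulations with no change, 2 of 440 list tests were called. The simulated genes were drawn independently of each other, while the estimated correlation of the male-biased list was 0.71. That count therefore does not give the error rate of camera for correlated lists such as these. Figures were drawn with matplotlib 3.10.9.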

Results

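RNA was sequenced from 6 liver samples of male C57BL/6 mice aged 4 months, 3 with a knockout of Sesn3 (KO) and 3 wild type (WT). All the mice had eaten a diet rich in fat, with added cholesterol and the bile salt sodium cholate, for 4 weeks. Sesn3 encodes sestrin 3, one of a small family of stress-inducible proteins that act on mTORC1 and AMPK signalling. The count table held 24421 gene symbols, and the libraries summed to between 18882220 and 24098512 counts. Correlations of log CPM (read counts normalised to library size and scaled by TMM factors) ran from 0.976 to 0.985 within KO, from 0.948 to 0.978 within WT and from 0.911 to 0.955 between the genotypes, over genes, which are not independent replicates. The first principal component held 56.4% of the variance and placed the KO libraries apart from the WT libraries. The second held 21.4% and placed WT replicate 1 and WT replicate 2 at opposite ends.

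Sesn3 was low in every library labelled KO. It had 18, 18 and 16 counts in KO replicates 1 to 3 against 172, 200 and 195 in WT replicates 1 to 3, or 0.715 ± 0.0398 CPM (SD, n = 3) against 10.3 ± 1.31 CPM (SD, n = 3). The gene lies on chromosome 9 from 14275067 to 14333101 (mm10) and was 14.4-fold lower in KO (log2 fold change -3.84, SE 0.22, edgeR adjusted p = 0.00183). Counts are summed over the whole gene, so the remaining reads were not placed on exons. Sesn2 was 2.06-fold higher in KO, at 21.6 ± 1.15 against 10.5 ± 2.83 CPM (SD, n = 3 each; edgeR adjusted p = 0.0276), and missed the threshold without KO replicate 1, 2 or 3 or WT replicate 3, with an adjusted p of up to 0.111. Sesn1 was at 16.7 ± 0.945 against 14.7 ± 2.49 CPM (SD, n = 3 each), a log2 difference of 0.19 (SE 0.16) that did not pass (edgeR adjusted p = 0.495).

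**Figure D1:**
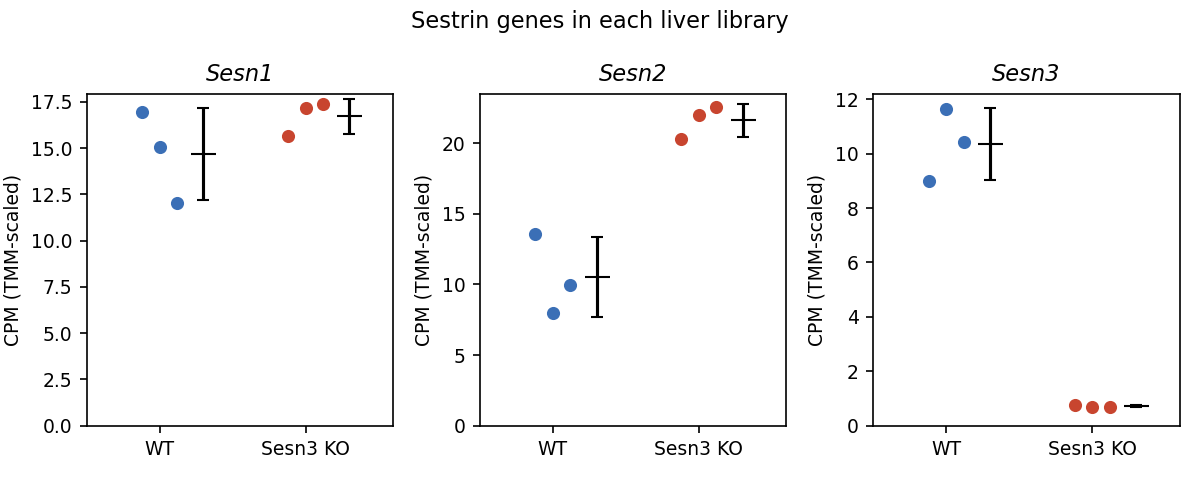
CPM, scaled by TMM factors, of Sesn1, Sesn2 and Sesn3 in each library (points), with the mean and SD of the 3 libraries of each genotype beside them (bars). Sesn3 averaged 0.715 CPM in KO and 10.3 CPM in WT.

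The comparison of KO with WT livers asks which hepatic transcripts differ between the genotypes on this diet. Large losses were in genes of the adult male liver and of lipid synthesis, among them Hsd3b5, a steroid dehydrogenase, Slco1a1, an organic anion transporter, and Thrsp, a lipogenic regulator. The gains included Fgf21, a fasting and stress hormone of the liver, H19, an imprinted non-coding RNA of fetal liver, the aldo-keto reductase Akr1b7, and collagens. Fgf21 rose from 1.14 ± 0.574 to 33.9 ± 4.60 CPM (SD, n = 3 each; log2 fold change 4.87, SE 0.34, edgeR adjusted p = 0.00212), H19 from 0.273 ± 0.0154 to 12.1 ± 5.43 CPM (log2 5.44, SE 0.48, adjusted p = 0.00421) and Akr1b7 from 1.21 ± 1.13 to 41.2 ± 11.5 CPM (log2 5.06, SE 0.57, adjusted p = 0.00693), with a log2 of 6.20 without WT replicate 1. Of 12945 genes tested, 435 were higher and 463 lower in KO.

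In all 898 of these genes the KO and WT libraries did not overlap. That held for 33.5% of the tested genes, against 10% by chance. Ifi44l, Vmn2r3 and Myo7b were close to absent in WT, with 1, 3 and 3 counts over the group, and their KO to WT ratios were 587 (95% counting interval 105 to 23206), 126 (42.8 to 612) and 39.6 (13.3 to 194). Il23a, a cytokine subunit, and Fosl1, an AP-1 subunit, rose from a low base (log2 4.70, SE 1.00, and 4.65, SE 0.99), and both missed the threshold in 5 of the 6 fits without 1 library, with an adjusted p of up to 0.128 and 0.107, and with limma-voom. Ifi44l reached a log2 of 10.9 (8.80 in the main fit) without WT replicate 1, and Vmn2r3 and Myo7b 10.2 and 6.03 (6.80 and 5.17) without WT replicate 3. Among abundant genes, Apoa4, an apolipoprotein, rose 8.55-fold to 6268 ± 1741 CPM (SD, n = 3), while Scd1, the stearoyl-CoA desaturase, fell 2.56-fold, Mup20 3.64-fold, Serpina3k 4.92-fold and Cyp2e1 3.86-fold. Without 1 library, Cyp2e1 missed the threshold in all 6 fits (adjusted p of up to 0.147), Scd1 and Mup20 in 5 (up to 0.171 and 0.180), Serpina3k in 3 (up to 0.0846) and Apoa4 in 2 (up to 0.0726). Scd1 and Mup20 also missed it with upper-quartile factors, with library size only and without robust dispersion, and Mup20 with limma-voom and the filter of 1 CPM in 3 libraries. Without KO replicate 1, 2 or 3 the counts of higher and lower genes were 144 and 151, 48 and 53, and 130 and 131, without WT replicate 3 they were 132 and 160, and without WT replicates 1 and 2 they were 504 and 458, and 405 and 475. Without scaling factors 707 were higher and 258 lower, with a median shift of all genes of 0.21 (log2), and DESeq2 called 924 and 1040.

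**Figure D2:**
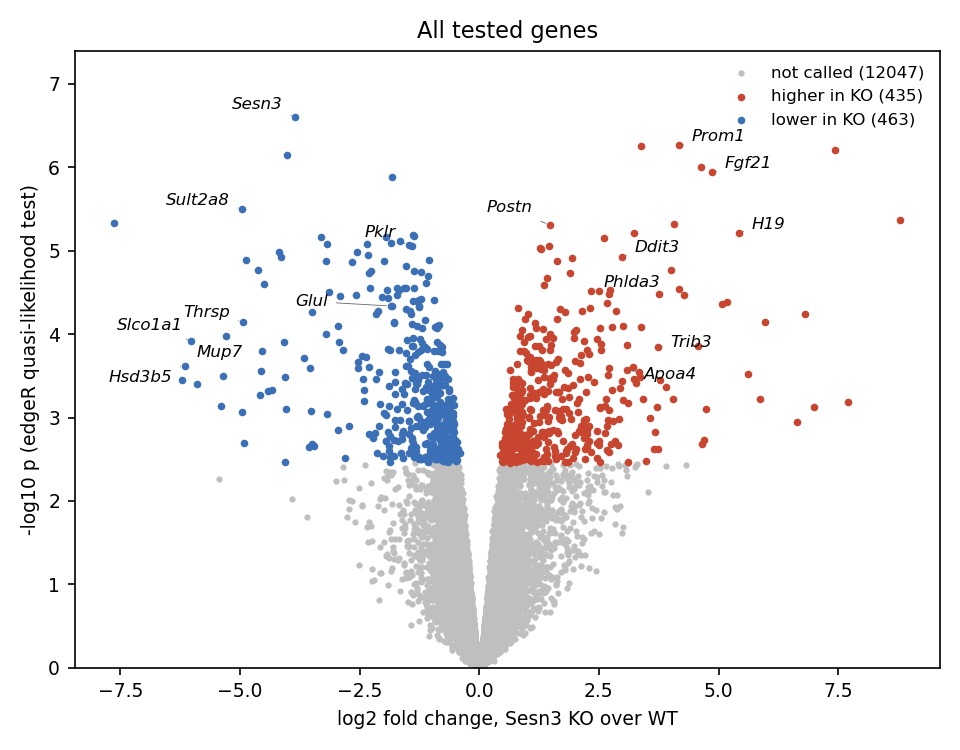
Log2 fold change fitted by edgeR (KO over WT, horizontal) against -log10 of the unadjusted p (vertical) for the 12945 tested genes, with 435 called higher (red), 463 called lower (blue) and the others in grey. Fold changes of genes with few WT counts are fitted values and depend on the prior count.

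Of 24 tested members of a list of genes that male liver expresses more than female liver, 19 fell and none rose, and 23 were lower when adjusted over the list alone. The median log2 fold change was -3.02 and every member was negative (adjusted p = 0.200 with an estimated correlation). Hsd3b5 went from 126 ± 129 CPM in WT to 1.75 ± 0.298 in KO (SD, n = 3 each; 71.4-fold lower, edgeR adjusted p = 0.015), Slco1a1 from 286 ± 210 to 4.43 ± 1.88 (64.7-fold, adjusted p = 0.0112) and the fatty acid elongase Elovl3 from 85.3 ± 93.1 to 2.01 ± 0.588 (42.4-fold, adjusted p = 0.0239). Cyp4a12a, Mup12 and Mup7 were 59.4-, 40.8- and 39.3-fold lower, Ugt2b1 5.85-fold, Cyp4a12b 18.2-fold, Mup21 17.7-fold and Susd4 11.3-fold. Outside the list, the organic anion transporter family gene Slc22a28 was 73.9-fold lower and the sulfotransferase Sult2a8 31.1-fold lower. Slc22a28 missed the threshold without KO replicate 1, 2 or 3 or WT replicate 3 (adjusted p of up to 0.0888) and with limma-voom (adjusted p = 0.0926). With limma-voom Mup12 (adjusted p = 0.0926), Elovl3 (0.0919), Cyp4a12a (0.0563), Hsd3b5 (0.0541) and the female-biased Cyp2a4 (0.0983) also missed it, and so did Elovl3 with no filter on low counts (adjusted p = 0.0600). Without WT replicate 2 the log2 fold change of Hsd3b5 went from -6.16 to -4.90, Elovl3 from -5.41 to -4.01, Slc22a28 from -6.21 to -5.30, Mup7 from -5.30 to -4.63 and Slco1a1 from -6.02 to -5.39. The WT spread was wide: Hsd3b5 was at 28.5, 271 and 76.7 CPM and Elovl3 at 16.5, 191 and 48.1 CPM in WT replicates 1, 2 and 3. Sult2a8, Ugt2b1, Cyp4a12b, Mup21 and Susd4 passed without each library in turn. Without KO replicate 2 the adjusted p was 0.0777 for Hsd3b5, 0.0633 for Slco1a1 and 0.109 for Elovl3, and 5, 7 and 10 of the 24 members passed without KO replicates 2, 3 and 1. Of 27 listed female-biased genes only 15 had enough counts to be tested, and the others stayed below the filter. Of the 15 tested genes, 4 rose and none fell (6 rose when adjusted over the list alone, median 1.56, adjusted p = 0.340 with an estimated correlation). Prom1 is also in the cholangiocyte list and Lpl in the macrophage list. The 4 risers are named next. They were Prom1 (18.1-fold), Cyp2a4 (16.4-fold), Abcd2 (log2 fold change 2.72) and Lpl (4.00-fold), of which 1 passed without KO replicate 2, 2 without KO replicate 3 and 1 without WT replicate 3. Mup, Cyp2a, Cyp4a, Serpina and Sult2a genes have near-identical copies, so the values of single members are uncertain.

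**Figure D3:**
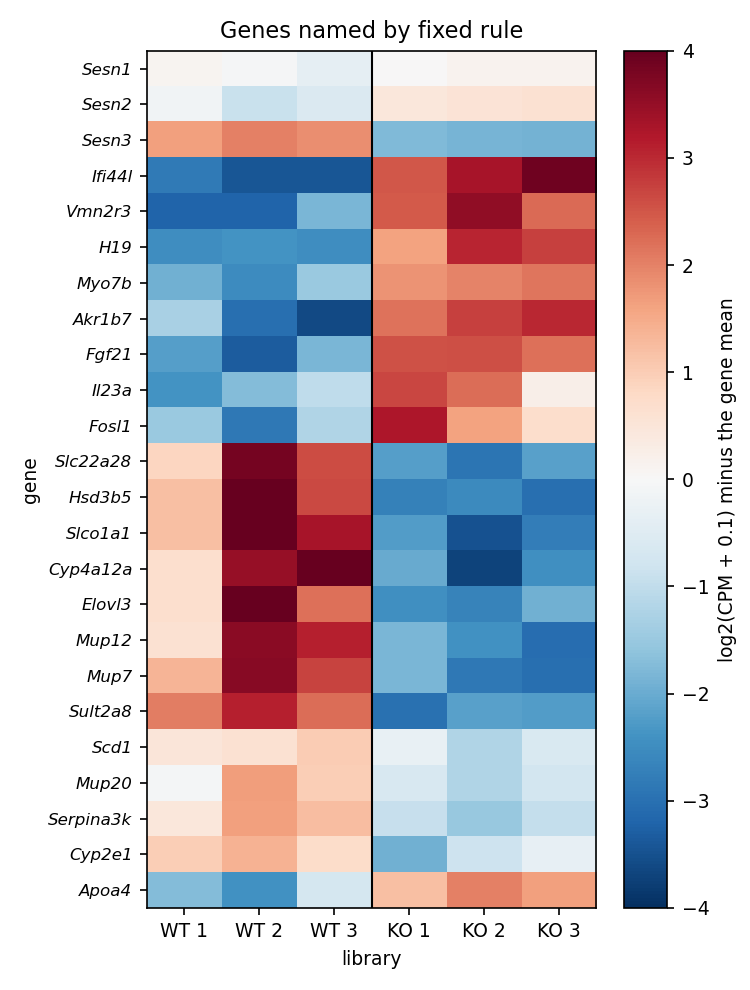
Log2(CPM + 0.1) minus the gene mean, colours limited at 4 in each direction, for the 24 sestrin, most changed and most abundant called genes (rows) in the 3 WT and 3 KO libraries (columns). WT replicate 1 holds smaller positive values than WT replicates 2 and 3 for genes such as Hsd3b5, Cyp4a12a and Elovl3.

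In the fatty acid and triglyceride synthesis list 10 of 23 tested genes fell and none rose, 17 when adjusted over the list alone, with a median of -0.95 (adjusted p = 0.0508 with an estimated correlation). Pklr, the liver pyruvate kinase, fell 2.78-fold from 229 ± 7.73 to 82.2 ± 12.1 CPM (SD, n = 3 each; edgeR adjusted p = 0.00421). Thrsp fell 30.8-fold, Acacb, an acetyl-CoA carboxylase, 5.12-fold and Acss2, an acetyl-CoA synthetase, 2.47-fold. Thrsp was at 450, 125 and 130 CPM in WT replicates 1 to 3, its log2 fold change of -4.95 was -4.06 without WT replicate 1, and it missed the threshold without KO replicate 1 or 2 (adjusted p of up to 0.0595). In the cholesterol synthesis list 12 of 26 fell and none rose, 17 when adjusted over the list alone (median -0.78; adjusted p = 0.295 with an estimated correlation). Among them were Fdps (3.67-fold), Stard4 (2.59-fold) and Nsdhl (2.06-fold). Pklr passed without each library in turn. Without KO replicates 1, 2 and 3 the lower genes of the first list that passed numbered 3, 1 and 3, and 5 without WT replicate 3. Of the second list 4, 0 and 2 passed without KO replicates 1, 2 and 3, and 6 without WT replicate 3.

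Of 41 tested fatty acid oxidation genes and PPAR-alpha targets, 6 rose and none fell (7 higher and 1 lower when adjusted over the list alone), and the median was 0.09 and the mean 0.60 (adjusted p = 0.779 with an estimated correlation). The risers were Fgf21, the acyl-CoA thioesterase Acot2 (10.4-fold, edgeR adjusted p = 0.00183), the omega-hydroxylases Cyp4a31 (23.9-fold), Cyp4a14 (9.42-fold) and Cyp4a10, and Crat. Cyp4a31 went from a log2 of 4.58 to 5.31 without WT replicate 1. Acot2 and Fgf21 passed without each library, and 2 and 3 members passed without KO replicates 2 and 3. In the list of lipid uptake, droplet and lipoprotein genes 3 of 40 rose (Apoa4, the phospholipid transfer protein gene Pltp at 2.63-fold and the droplet coat gene Plin2 at 2.46-fold) and 3 fell, Slc27a5 and Fabp1 among them, with 4 each way when adjusted over the list alone. That list was not called, and its median of -0.13 and mean of 0.10 differ in sign. None of its 40 genes passed without KO replicate 2, and 3 without KO replicate 3.

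Of 21 tested genes of pericentral hepatocytes 8 fell and 1 rose, 11 and 1 when adjusted over the list alone (median -1.09; adjusted p = 0.295 with an estimated correlation). Glul, the glutamine synthetase, fell from 1162 ± 103 to 322 ± 77.2 CPM (SD, n = 3 each; 3.61-fold, edgeR adjusted p = 0.0071), the glutamate transporter Slc1a2 fell 5.99-fold, Cyp2c37 9.21-fold and Cyp1a2 2.91-fold. The riser was the amino acid transporter Slc1a4. Glul and Slc1a2 passed without each library, and 4, 2 and 5 of the 21 passed without KO replicates 1 and 2 and WT replicate 3. Periportal genes moved both ways: 4 of 21 rose (Apoa4, Cdh1, Aldh1b1, Hsd17b13) and 2 fell (Cyp2f2 at 3.42-fold, Pigr), 5 and 2 when adjusted over the list alone, and the list was not called. Of these periportal genes 3, 0, 1 and 2 passed without KO replicates 1, 2 and 3 and WT replicate 3. In xenobiotic metabolism 12 of 35 fell and 3 rose, 17 and 3 when adjusted over the list alone (median -0.78; adjusted p = 0.364 with an estimated correlation). Cyp2c54 fell 22.5-fold and Cyp2c50 9.24-fold, while Cyp2c55 rose 6.63-fold beside Cyp2b10 and Cyp2a4. Of these 35 genes 10, 4, 10 and 9 passed without KO replicates 1, 2 and 3 and WT replicate 3. Of 28 bile acid genes 8 fell and 2 rose, 11 and 3 when adjusted over the list alone (median -0.46; adjusted p = 0.448 with an estimated correlation). The fallers included Sult2a8, Slco1a1 and Cyp7b1 (5.82-fold), an oxysterol hydroxylase, and the risers were the basolateral exporters Abcc4 (4.41-fold) and Slc51b. Of these 28 genes 4, 2, 5 and 4 passed without KO replicates 1, 2 and 3 and WT replicate 3. The called genes of these lists are not separate counts. Of the 9 called pericentral genes 4 are also called in the xenobiotic list and 1 in the bile acid list. Of the called xenobiotic genes 2, and of the called bile acid genes 2, are also called in the male-biased list. Cyp2c and Cyp4a genes share the uncertainty of multigene families.

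In the complement and coagulation list 9 of 35 genes fell and none rose, 16 when adjusted over the list alone (median -0.55; adjusted p = 0.397 with an estimated correlation), with C8b 3.45-fold, Mbl1 2.56-fold, C9 2.45-fold and C1ra 1.79-fold lower. Mbl1 passed without each library, while 3, 1, 2 and 3 of the 35 passed without KO replicates 1, 2 and 3 and WT replicate 3, and 5 without WT replicate 2, and C1ra missed the threshold with library size only. In the acute-phase list Crp (2.06-fold), Saa4 (2.54-fold) and Saa2 (10.9-fold) fell and Hamp, the iron hormone hepcidin, rose 3.27-fold, 4 of 28 in all, with 7 lower and 2 higher when adjusted over the list alone. That list was not called. Saa2 was at 972, 104 and 442 CPM in WT replicates 1 to 3, its log2 fold change of -3.45 was -2.56 without WT replicate 1, and it missed the threshold without KO replicate 1, 2 or 3 or WT replicate 3 (adjusted p of up to 0.143) and with no filter on low counts (adjusted p = 0.0942). Passing genes of the list numbered 1, 0, 1 and 2 without KO replicates 1, 2 and 3 and WT replicate 3, and 8 lower and 1 higher passed without WT replicate 2.

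In the ATF4 and integrated stress response list 11 of 25 rose and 1 fell, 14 and 2 when adjusted over the list alone (median 1.09; adjusted p = 0.166 with an estimated correlation). Besides Fgf21 they included Ddit3 (7.93-fold, from 4.65 ± 1.26 to 37.0 ± 11.5 CPM, SD, n = 3 each; edgeR adjusted p = 0.00429), the pseudokinase gene Trib3 (13.3-fold) and Atf4 itself (2.11-fold). The faller was Chac1. Trib3 went from a log2 of 3.74 to 4.42 without WT replicate 2. Ddit3 passed without each library, and 4, 2, 5 and 4 of the 25 passed without KO replicates 1, 2 and 3 and WT replicate 3. Of 21 p53 targets 13 rose and none fell, 15 when adjusted over the list alone (median 1.04; adjusted p = 0.134 with an estimated correlation), among them Phlda3 (5.02-fold), Aen (2.37-fold), Zmat3 (2.26-fold) and Plk2 (2.13-fold). Phlda3 passed without each library, and 4, 1, 3 and 6 of the 21 passed without KO replicates 1, 2 and 3 and WT replicate 3. Sesn2 and Gdf15 are in both lists.

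Other stress lists held fewer calls. In the unfolded protein response 3 of 24 fell and none rose, 14 lower and 1 higher when adjusted over the list alone (median -0.67; adjusted p = 0.552 with an estimated correlation): Derl3 fell 7.76-fold, Creld2 3.37-fold and Dnajb11 1.88-fold. With library size only Creld2 and Dnajb11 missed the threshold. Of the 24 genes 5, 0, 1 and 1 passed without KO replicates 1, 2 and 3 and WT replicate 3. Of 26 immediate early and heat shock genes 5 rose (Atf3 at 8.60-fold, Fos at 3.53-fold, Egr1 at 2.71-fold, Fosb and Jund) and Hspe1 fell 1.51-fold, 8 and 3 when adjusted over the list alone (median 0.42; adjusted p = 0.658 with an estimated correlation). Atf3 missed the threshold with no filter on low counts (adjusted p = 0.0522), Fos with limma-voom (adjusted p = 0.0847), and Hspe1 with upper-quartile factors and library size only. Passing genes of that list numbered 2, 0, 1 and 0 without KO replicates 1, 2 and 3 and WT replicate 3. Of 36 NRF2 and glutathione genes Abcc4 rose and Gsta3, Gstp1 and Sod2 fell, 3 and 7 when adjusted over the list alone, and the list was not called. Gstp1 and Sod2 missed the threshold with library size only. In that list 1 gene passed in each fit without KO replicate 1, 2 or 3 or WT replicate 3. In the cell cycle list Ccnd1 (4.37-fold) and Cdc20 (7.46-fold) rose, 2 of 35 on either adjustment (median 0.94; adjusted p = 0.681 with an estimated correlation). Both missed the threshold with no filter on low counts (adjusted p = 0.0520 and 0.0686), and Cdc20 with limma-voom (adjusted p = 0.0590). No cell cycle gene passed without KO replicate 1, 2 or 3 or WT replicate 3, and 4 were higher without WT replicate 1 or 2.

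All 42 tested members of the extracellular matrix and fibrosis list had positive log2 fold changes, 19 rose and none fell, and 29 were higher when adjusted over the list alone (median 1.38; adjusted p = 0.299 with an estimated correlation). Postn, periostin, went from 9.94 ± 1.01 to 27.5 ± 0.612 CPM (SD, n = 3 each; 2.77-fold, edgeR adjusted p = 0.00421), Fbln5 rose 3.71-fold, the macrophage elastase Mmp12 5.53-fold and Col14a1 1.81-fold. Col1a1 rose 6.98-fold and Col1a2 4.92-fold, and both missed the threshold without KO replicate 1, 2 or 3 or WT replicate 3 (adjusted p of up to 0.106 and 0.111) and with no filter on low counts (0.0636 and 0.0599). Without WT replicate 1 the log2 fold change of Col1a1 went from 2.80 to 3.42. Postn and Fbln5 passed without each library, while 4, 2, 7 and 4 of the 42 passed without KO replicates 1, 2 and 3 and WT replicate 3. Of 23 TGF-beta response genes 6 rose and none fell, 11 when adjusted over the list alone (median 0.85; adjusted p = 0.340 with an estimated correlation). They included Cyr61 (2.37-fold) and Ltbp2 (4.27-fold), and 4 of the 6 (Col1a1, Col1a2, Col3a1, Ltbp2) are also in the matrix list. The response genes that passed numbered 0, 0, 2 and 0 without KO replicates 1, 2 and 3 and WT replicate 3. Of 30 TGF-beta pathway components Ltbp3 and Tgfb2 rose, 2 on either adjustment, and the list was not called. Neither passed without KO replicate 1, 2 or 3 or WT replicate 3, and 1 component was higher without WT replicate 2 and 4 without WT replicate 1.

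Of 25 markers of recruited and lipid-associated macrophages 5 rose (Mmp12, Trem2 at 6.17-fold, Lpl, Cd9 at 2.03-fold and Cd63) and none fell, 7 when adjusted over the list alone (median 0.90; adjusted p = 0.533 with an estimated correlation). Without KO replicates 1, 2 and 3 and WT replicate 3, 2, 0, 2 and 2 of them passed, and 11, all higher, without WT replicate 1, where the log2 fold change of Trem2 went from 2.62 to 3.44. Of 17 Kupffer cell markers Clec4f and Vsig4 rose, 4 when adjusted over the list alone, and the list was not called. Neither passed without KO replicate 1, 2 or 3 or WT replicate 3, and 7 higher and 1 lower passed without WT replicate 1 and 1 without WT replicate 2. Of 23 stellate cell and myofibroblast markers Pdgfra rose 2.24-fold, with 8 higher and 1 lower when adjusted over the list alone (median 0.27; adjusted p = 0.448 with an estimated correlation). It missed the threshold without KO replicate 2 (adjusted p = 0.0669) and without WT replicate 3, and 3 markers were higher without KO replicate 3 and 2 without WT replicate 1. Of 23 liver endothelial markers Dnase1l3 fell 2.76-fold, 1 on either adjustment, and the median was -0.53 (adjusted p = 0.708 with an estimated correlation). It missed the threshold without KO replicates 1, 2 and 3 and WT replicate 3 (adjusted p of up to 0.101) and with library size only, and 2 of the markers were lower without WT replicate 2. Of 16 cholangiocyte markers Prom1 rose, with 2 higher when adjusted over the list alone (median 0.42; adjusted p = 0.166 with an estimated correlation). Of 7 erythroid markers Car1 (7.65-fold) and Alas2 (4.19-fold) fell, 4 when adjusted over the list alone (median -1.27; adjusted p = 0.200 with an estimated correlation). Without KO replicates 1, 2 and 3, 1, 0 and 1 of the erythroid markers passed, and 3 without WT replicates 1 or 2. In edgeR no gene passed among 11 B cell and plasma cell markers (median 0.86; adjusted p = 0.448 with an estimated correlation), 21 T and NK cell, 13 dendritic or 7 neutrophil markers. At an unadjusted p under 0.05 there were 4, 2, 4 and 0 of them, and DESeq2 called 2, 1, 4 and 0. When adjusted over the list alone 2 dendritic markers were higher and 2 lower, and none of the other 3 sets passed. Leaving out WT replicate 1 gave 1 B cell, 1 T and NK cell and 1 dendritic marker, all higher, and leaving out WT replicate 2 gave 2 lower dendritic markers.

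In the other metabolic lists few genes passed. Of 41 nuclear-encoded oxidative phosphorylation genes Ndufb3 fell 1.47-fold (edgeR adjusted p = 0.0317), all 41 were negative with a median of -0.31, and none passed over the list alone (adjusted p = 0.658 with an estimated correlation). Ndufb3 missed the threshold in 5 of the 6 fits without 1 library, with an adjusted p of up to 0.101, and with library size only (adjusted p = 0.135). Of 31 gluconeogenesis and glycolysis genes Pklr, Pfkfb3 (2.41-fold), Pfkfb1 (1.97-fold) and Pygl (1.79-fold) fell, 4 on either adjustment (median -0.27; adjusted p = 0.448 with an estimated correlation). Without KO replicates 1 and 2 and WT replicate 3, 2, 1 and 2 of these passed. Pygl missed the threshold in all 6 fits without 1 library (edgeR adjusted p of up to 0.177) and with library size only. Of 32 amino acid and urea genes Glul and Kmo (1.55-fold) fell and Gpt2 (1.99-fold) rose, 3 and 1 when adjusted over the list alone (median -0.22; adjusted p = 0.824 with an estimated correlation). Of the 32, 2 passed without KO replicate 1 and 1 without each other library. Kmo missed the threshold in all 6 fits without 1 library (edgeR adjusted p of up to 0.170) and with library size only. Among those 6 fits Gpt2 passed only in the fit without KO replicate 1 (edgeR adjusted p of up to 0.167 in the others). Of 33 autophagy and lysosome genes Sqstm1 rose, and of 38 interferon response genes Ifi44 rose, and neither passed over its list alone. Ifi44 missed the threshold without KO replicate 1, 2 or 3 or WT replicate 1, and the interferon list had a median of -0.18 with 26 of 38 members negative. Without WT replicate 2, 15 interferon genes were lower and 1 higher. Sqstm1 missed it without KO replicate 1, 2 or 3 or WT replicate 3. In edgeR no gene passed, over all genes or over the list alone, among 35 mTORC1, GATOR and AMPK components, 44 cytosolic ribosomal proteins, 22 clock genes, 17 antigen presentation genes or 30 inflammatory cytokines and chemokines. At an unadjusted p under 0.05 there were 8, 2, 5, 3 and 6 of them, and DESeq2 called 3, 0, 4, 2 and 4. Leaving out WT replicate 2 gave 4 lower antigen presentation genes, 3 lower cytokines or chemokines and 1 higher clock gene, and leaving out WT replicate 1 gave 1 higher clock gene and 1 lower mTORC1, GATOR or AMPK component. Of 8 tested gallbladder, gut and mesothelium markers Apoa4 and Tff3 rose, with 2 higher and 2 lower when adjusted over the list alone, and 1 passed without KO replicate 2 or 3. Of 22 listed neighbours of Sesn3 on chromosome 9 none passed in edgeR on either adjustment, against 2 at an unadjusted p under 0.05, 1 by DESeq2 and 1, lower, without WT replicate 1. That list covers part of the region, and the called gene Mmp12, which lies within 20 Mb of Sesn3, is not in it. Of 9 genes that differ between C57BL/6 substrains Nnt rose (log2 0.63) and Ide fell (log2 -1.22), as they did when adjusted over the list alone, and 0, 0, 1 and 1 passed without KO replicates 2 and 3 and WT replicates 1 and 3.

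**Figure D4:**
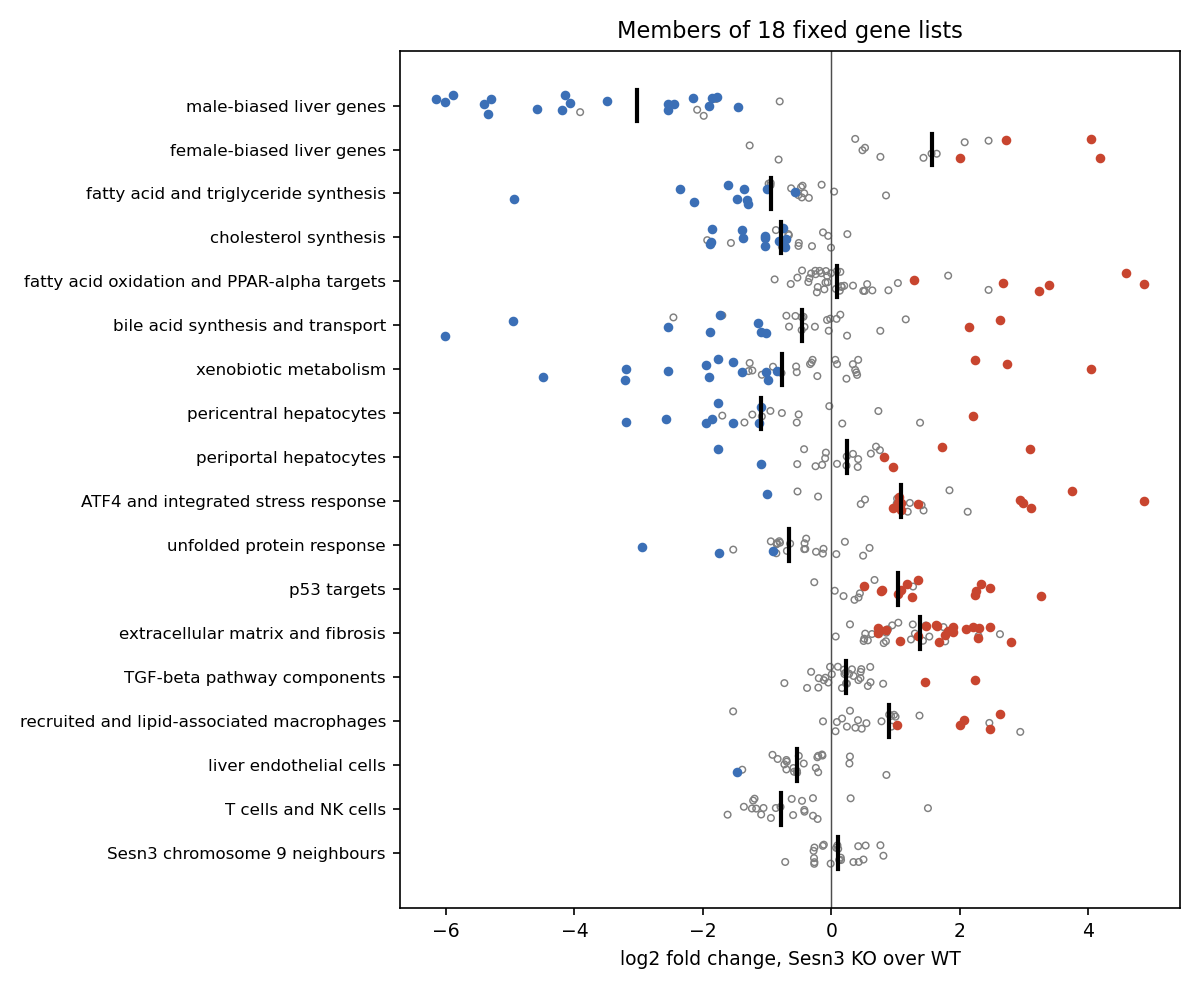
Log2 fold change fitted by edgeR (KO over WT, horizontal) of each tested member of 18 fixed gene lists (rows), with called genes filled (red higher, blue lower), other genes open and the list median as a black bar. Male-biased genes had a median of -3.02 and matrix genes a median of 1.38.

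By camera with a preset correlation, 12 of the 44 tested lists were called up and 13 down, and with an estimated correlation none was (lowest adjusted p = 0.0508, with 6 lists at an unadjusted p under 0.05). With fry, which tests each list alone, 4 lists were called up and 6 down.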

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

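The settings were planned before the data were examined, and those for normalized values (a pseudocount and a filter on low values) were not run because the table holds counts. Sesn3 kept its direction and its side of the threshold in all 14 alternatives, between -3.93 and -3.63 (log2), with an adjusted p of up to 0.0208. The counts of 435 higher and 463 lower genes became 707 and 258 with library size only, which raised the higher share from 48.4% to 73.3%, 924 and 1040 with DESeq2, and 282 and 242 with a log2 fold change of at least 1. The cause of the DESeq2 difference was not tested. Without 1 library they ranged from 48 to 504 higher and from 53 to 475 lower, with fewer samples in the fit. Of the 103 called named genes, 26 passed without each library in turn and 77 lost the call in at least 1 such fit, and none changed sign there. Without KO replicate 2, 77 named genes lost the call, as did 12 with library size only, 11 with limma-voom, 7 with no filter on low counts, 3 with upper-quartile factors, 2 without robust dispersion, 1 with the filter of 1 CPM in 3 libraries and 0 with RLE factors or DESeq2. Beside the moves given with the results, the log2 fold change went without WT replicate 1 from 3.10 to 3.80 for Atf3 and from 2.90 to 3.54 for Cdc20, and without WT replicate 3 from 3.10 to 3.69 for Apoa4, from -5.89 to -5.27 for Cyp4a12a, from 4.70 to 5.94 for Il23a and from 4.65 to 5.24 for Fosl1, which was at 3.61 without KO replicate 1. Called lists numbered 12 up and 13 down, 0 and 0 with the correlation estimated per list, and 4 and 6 with fry, which tests the list alone.

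The direction given by camera, which weighs all members and can differ from the sign of the median, changed in at least 1 setting for 8 lists, 0 of them called. The median of 13 lists changed sign, 1 of them called (fatty acid oxidation and PPAR-alpha targets, without KO replicate 3). Among the 8, the NRF2 and glutathione median was 0.35 with library size only and -0.0478 to 0.42 without 1 library, and that of neutrophils was 0.0071 with the filter of 1 CPM in 3 libraries and -0.55 to 0.55 without 1 library. The C57BL/6 substrain median was 0.0141 with limma-voom and -0.0775 to 0.29 without 1 library. Without 1 library the medians ran from -0.30 to -0.0222 for lipid uptake, droplets and lipoproteins, -1.0003 to -0.0831 for T cells and NK cells, -0.33 to 0.13 for the acute-phase response, -0.24 to 0.47 for dendritic cells and -0.22 to 0.69 for inflammatory cytokines and chemokines. The cause was not tested. In simulation at this depth and spread, 6% of the changes of 1.5-fold were recovered. Far fewer genes were changed in that simulation than the 898 called in the data. Recovery after Benjamini-Hochberg adjustment depends on how many genes change, so the 6% does not give the recovery in the data.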

Other observations

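Saa1, a serum amyloid gene, was at 2181, 218 and 651 CPM in WT replicates 1, 2 and 3 and at 128 ± 23.3 CPM in KO (SD, n = 3; edgeR adjusted p = 0.0616). Cxcl9, a chemokine induced by interferon gamma, was at 391, 31.4 and 266 CPM in WT replicates 1 to 3 against 34.9 ± 15.6 in KO (SD, n = 3; edgeR adjusted p = 0.0927), and the interferon-induced GTPase gene Igtp at 447, 30.1 and 149 CPM against 34.6 ± 10.3 (SD, n = 3; edgeR adjusted p = 0.110). Of 7 tested fetal and imprinted growth genes, in a list also made after the results were seen, H19 was the 1 called over all genes, and 2 were higher and 1 lower when adjusted over the list alone. Afp, alpha-fetoprotein, was at 3.29 ± 1.22 CPM in KO and 1.13 ± 0.650 CPM in WT (SD, n = 3 each; edgeR adjusted p = 0.0937), and Gpc3, glypican 3, was lower in value at 0.554 against 1.24 CPM (edgeR adjusted p = 0.111). Ghr, the growth hormone receptor gene, was lower in KO (log2 -1.72, SE 0.20, edgeR adjusted p = 0.00626), and so was Egfr (log2 -2.15, edgeR adjusted p = 0.00752). Egfr is a member of the male-biased list and is already counted among the genes that fell there. The genes of this paragraph were picked after their values were seen.

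The explanations weighed in the rest of this part, and their predictions, were chosen after the results were seen, while the fits without 1 library and the lists of male-biased, matrix, endothelial, stellate and substrain genes were fixed before. For the genes far apart between the groups, the share of called genes near Sesn3 was tested first, and the count of positions was added after the value of that test was known. For the mesothelial genes, the requirement of a level above 1 CPM was also added after their values were known.

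Of 24 male-biased genes 19 were called lower in KO and none higher (list median -3.02; adjusted p = 0.200 with an estimated correlation). Female or mixed tissue is argued against by the female-expressed transcript Xist, at 0.0845, 0.0386 and 0 CPM in KO replicates 1 to 3. The sum of Y-linked genes in each KO library was at least 84.7% of the WT mean. That sum alone would not exclude a small share of female tissue. Of the Y-linked genes Eif2s3y alone was called lower (log2 -0.64). A hepatocyte loss as large as the fall of this list is argued against by 15 secreted-protein genes. They had a median of -0.25, with 11 negative and none called. A smaller loss stays open, since complement and coagulation genes had a median of -0.55, with 33 of 35 negative and 9 called lower. The difference does not rest on 1 library, since the list median was at most -2.66 without each library, although only 5 to 10 of the 24 passed without single KO libraries. Reduced growth hormone signalling stays open: Igf1, Igfals, Socs2 and Cish had a median of -0.52 and none was called, although Ghr was. The knockout itself may be the source, and the groups of 3 cannot separate it from other differences between these mice.

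Of 42 matrix genes 19 were called higher in KO and none lower (list median 1.38; adjusted p = 0.299 with an estimated correlation). The endothelial list did not rise with the matrix genes: its median was -0.53 and 20 of 23 members were negative. It had 1 called member, and its adjusted p was 0.708 by camera with an estimated correlation, which was 0.62. Its members move together, and their levels do not measure cell numbers. A rise of all non-hepatocyte cells alike therefore stays open. More liver capsule stays open, since the 4 tested mesothelial genes (median -1.21) averaged under 1 CPM in KO and exclude nothing. More stellate cells or myofibroblasts also stay open, since that list had a median of 0.27 and 1 called member. Recruited macrophages may contribute to Mmp12, which is in both lists, and their number was not measured. Mmp12 also starts at 7344381 on chromosome 9, within 20 Mb of Sesn3. An effect on Mmp12 of DNA linked to Sesn3 cannot be told apart from the knockout.

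The groups differed by a log2 of at least 4 in 51 called genes. Of the tested genes within 20 Mb of Sesn3, 5.43% were called, against 6.94% elsewhere (two-sided Fisher's exact p = 0.603, odds ratio 0.769 with an interval of 0.302 to 1.64), which leaves open whether DNA of another strain around Sesn3 changed its neighbours. Sequence differences linked to Sesn3 in the large-difference genes themselves are argued against, since all 48 with a known position lie outside that window. Unlinked substrain differences may contribute and cannot be told apart from genotype: Nnt differed by 0.63 (log2), and the substrain of each mouse is not given in the sources used here.

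The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The real split called 898 genes and the highest of the others 0, so 1 of 10 splits gave as many. The real split called 25 lists and the highest of the others 31, so 4 of 10 splits gave as many lists, so a preset correlation also calls lists between groups that mix the genotypes.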
